A study of Caenorhabditis elegans with 9 samples.

How the data were processed

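The data are the log ratios of 9 spotted 2-colour arrays of C. elegans total RNA, 3 each from wild type, a hif-1 mutant and a vhl-1 mutant. On each array, per the labels, the RNA called H was labelled with Cy3 in channel 1 and the RNA called N of the same genotype and replicate number with Cy5 in channel 2. The deposited values, 1 per spot and array, were read as log2 ratios of the channels that the authors had already brought close to a median of 0 on each array. They are symmetric around 0 with 3 decimals, and their array medians ran from -0.062 to 0.061. Neither the base of the logarithm nor the direction of the ratio is stated in the sources used here: base 2 and channel 2 over channel 1 (N over H, as the sample titles are worded) were assumed before the data were examined, and the sign was turned so that positive values mean more RNA in H. With another base every log2 value would scale by one factor and every fold would be raised to one power, and with the other direction every sign would turn, while no p-value would change. Image analysis, background and normalisation before deposition are not given in the sources used here. The spot intensities were not used here, so signal over background is unknown.

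The table held 21888 spots. Cells marked null (3303) and empty cells (1156) were taken as missing, which left 401 to 592 spots per array without a value. Of the spots, 7774 (35.5%) had 1 gene name in the platform's annotation, 0 had several and 14114 had none. The names were updated through the gene identifiers of a table of the WBcel235 assembly, in which 7741 spots were matched; this table also gave the positions. There were 7200 distinct names, and 562 genes had more than 1 spot. The mutated genes hif-1 and vhl-1 are not among the names, so the genotypes were not checked in the values.

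Each array was centred on its median. Spots with values on at least 2 arrays of every genotype were kept (21431), spots of one gene were averaged per array, and 20858 features, 7179 named genes and 13679 unnamed spots, were tested. limma 3.58.1 in R 4.3.3, with statmod 1.5.0, was used to fit 1 mean per genotype to all 9 arrays (lmFit and eBayes; 6 residual degrees of freedom, prior degrees of freedom 6.95, median residual SD 0.46), with a test of each genotype's response against 0, of the 3 differences between genotypes, of the mean over genotypes, and a moderated F test for any difference among genotypes. p-values were adjusted by Benjamini and Hochberg over all features and a result passed at an adjusted p under 0.05. The p-values measure the spread between these samples; the labels do not say whether the replicates were separate cultures. The median SE was 0.266 for a response in one genotype and 0.376 for a difference between genotypes, and the 3 arrays per genotype limit the precision.

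Comparisons, tests, gene lists and the rule for named genes were set before the data were examined. In each comparison the rule named, among genes past the threshold with the same sign on every array (or, for differences, with no overlap between genotypes), the 10 highest and 10 lowest. Where fewer passed it added the 5 genes with the lowest p, and in every comparison 9 genes of the HIF pathway, of which only F22B5.4 had a named spot, and up to 4 genes with the lowest p of each list. Genes and spots named outside the rule, CYTB in the mean, the members of gene families and the unnamed spots probe_4338 and probe_21826, were chosen after their values were seen. The 32 lists covered the HIF pathway and its targets, stress responses, metabolism, tissues, germ line and cell growth. Of these, 11 had a named member and 4 had the minimum of 3 needed for a test (respiratory chain, collagens, neuropeptide-like genes and translation factors). Lists were tested with limma's cameraPR, the form of camera for values ranked beforehand, with a preset correlation of 0.01, because camera itself takes no missing values. camera with an estimated correlation and fry were run on features with all 9 values. The p-values of the lists were adjusted over lists and contrasts together. Correlations of mean responses are across features, which are not independent replicates.

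The procedure was tested on simulated data with this design and spread in 5 simulations with 250 changed features per size. Of responses of 1 log2 unit 25.6% were recovered and of those of 2 units 98.4%; of differences between genotypes of 1 unit 4% and of 2 units 77.6%. Among 103290 unchanged features, 41 and 26 were called. The errors were drawn independently for each feature and array, without deviations that many features of an array share. The calls among unchanged features may therefore be too few for real arrays. Each simulation held changes of 0.5 to 3 units together, which eases the adjusted threshold. The recovered shares may therefore be too high for a comparison in which few features pass.

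The alternatives set beforehand were values as deposited, arrays scaled to one median absolute deviation, only features with all 9 values, no filter on missing values, each spot alone, robust eBayes, a threshold of 0.10, replicate number as a block, only the arrays of the genotypes compared, and each of the 9 arrays left out in turn. Chosen after seeing the data were centring on the median of each of 32 print runs, centring in addition on the place within the run (2 places either side), named genes alone, leaving out the 87 of 684 places where no run has a named spot, and 24 lists of gene families and complexes made from the names of measured genes. The print runs, also called print blocks here, were read from the spot numbers, which repeat every 702. All 32 lie on every array, so the term does not mean batches of arrays. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. No array was left out of the main tests.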

Results

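The 9 arrays compared RNA labelled H with RNA labelled N in C. elegans, with 3 arrays for each of 3 genotypes and both RNAs of an array from one genotype. The series is titled for the response to hypoxia, so H is read here as hypoxia and N as normoxia. The genotypes were wild type, a hif-1 mutant and a vhl-1 mutant. hif-1 encodes the alpha subunit of the hypoxia-inducible transcription factor, and vhl-1 the ubiquitin ligase subunit that recognises HIF-1 for degradation. Each array carried 21888 spots and gave a value for 21296 to 21487 of them. After filtering, 20858 features could be tested, of which 7179 were named genes and 13679 were single spots without a gene name. The regulators hif-1, vhl-1, egl-9, rhy-1 and aha-1 and the genes nhr-57, phy-2 and cysl-2 were not among the named spots, so neither mutation could be checked in these values. Across features, which are not independent replicates, the correlation between arrays ran from 0.0722 to 0.703 over the 36 pairs, with a median of 0.373. It was 0.217 to 0.505 within wild type, 0.184 to 0.319 within the hif-1 mutant and 0.518 to 0.703 within the vhl-1 mutant. Over the 27 pairs of arrays from different genotypes it ran from 0.0722 to 0.555, with a median of 0.374. That median lay above all pairs within the hif-1 mutant and above the median of 0.326 within wild type. Replicates of these 2 genotypes were thus mostly no more alike than arrays of different genotypes, which limits the comparisons between genotypes. Every array carried N in Cy5 and H in Cy3, so an effect of the dye on a single probe stays in each response and cancels between genotypes where it is alike. All changes below are given as log2 ratios of H over N, centred on each array's median. The direction is likely, not stated: it rests on the order of N and H in the sample titles and on the usual channel 2 over channel 1, and with the opposite reading every rise below would be a fall. The base of the logarithm is likewise assumed, and the tests depend on neither.

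The wild type arrays address which transcripts change in hypoxia when HIF-1 and its regulation are intact. F22B5.4, a gene used as a HIF-1 target (chromosome II, 8449710 to 8452742, WBcel235), was 2.26 ± 1.21 higher in H (SD, n = 3; SE of the fit 0.365, adjusted p = 0.00813), a 4.79-fold rise seen on 3 of 3 arrays. F26A3.4 (chromosome I, 7656978 to 7658291) rose by 2.98 ± 1.33 (SD, n = 3; adjusted p = 0.00916). hsp-16.21, of the small heat shock protein family (chromosome V, 14463520 to 14464428), rose by 2.1 ± 1.41 (SD, n = 3; adjusted p = 0.0295). Among the genes that fell, F41H10.4 was at -2.99 ± 1.48 (SD, n = 3; adjusted p = 0.00804), C18E9.5 at -1.80 ± 0.67 (n = 3; adjusted p = 0.00883) and erp-44.3, of a family of thioredoxin-like endoplasmic reticulum proteins, at -1.86 ± 0.53 (n = 2; adjusted p = 0.0160). Without wild type array 2 hsp-16.21 was at 1.32 (adjusted p = 0.287), F26A3.4 at 2.34 (0.117) and C18E9.5 at -1.76 (0.0825). Without array 3 these had adjusted p of 0.0981, 0.0778 and 0.1, and F41H10.4 of 0.0671. The call of hsp-16.21 was also lost with print block centring (0.0673), print layout centring (0.101), the unnamed places left out (0.0557) and the wild type arrays alone (0.057), and that of F26A3.4 with print layout centring (0.0567).

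The other genes with the largest rises in wild type were F59B10.4 (1.69), dpsm-1 (1.58), npr-37 of the neuropeptide receptor family (1.49), snrp-40.1, a homologue of a U5 snRNP protein (1.47), W04E12.4 (1.46), F02D10.2 (1.32) and T08G3.6 (1.30), with adjusted p from 0.0324 to 0.0466. Those with the largest falls were C17C3.2 (-2.73), T04C9.1 (-2.68), srlf-34 (-2.23), K05G3.2 (-2.2), Y106G6H.9 (-1.86), F49F1.7 (-1.77) and C11H1.7 (-1.70), with adjusted p from 0.00907 to 0.0432. Of the 20858 features, 296 passed the test in wild type, 47 higher and 249 lower in H (84.1% lower), and 2729 had an unadjusted p under 0.05 where chance gives 1043. The 34 named genes among them, 16 higher and 18 lower, each moved the same way on every array with a value, as did 38.7% of all features. Passing this test on 3 arrays itself favours a single sign, so this is no separate support. Of the 20 genes of largest change, 19 lost their call in at least 1 fit with an array left out, all but erp-44.3, which 5 of the 9 fits could test; npr-37 was at 0.96 without array 1 and C17C3.2 at -1.75 without array 3 (adjusted p = 0.201 and 0.111). The count depends on single arrays and on the unnamed spots: it was 107, all lower, without wild type array 2, where F22B5.4 had an adjusted p of 0.0795, and 82 without wild type array 3, where it had 0.0851. It was 540 (70.6% lower) with arrays scaled to one spread, 78 after centring on the print layout, 86 without the places that hold no named spot, and 0 in limma when named genes were tested alone (769 with an unadjusted p under 0.05, 359 by chance; adjusted p of F22B5.4 0.0511).

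**Figure D1:**
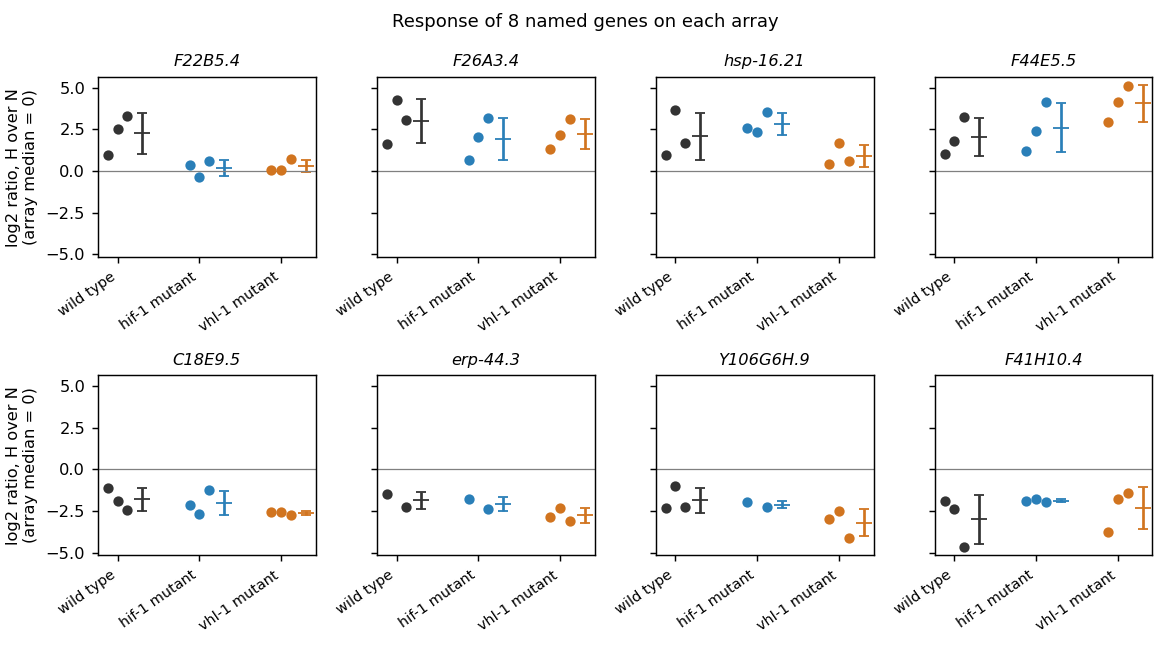
Log2 ratio of H over N (vertical axis, array median at 0) of 8 named genes on each array of the 3 genotypes, with points for arrays and bars for the mean ± SD. F22B5.4 averaged 2.26 in wild type, 0.21 in the hif-1 mutant and 0.30 in the vhl-1 mutant, whereas C18E9.5 was below 0 on all 9 arrays.

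In the hif-1 mutant the question is which changes still occur in hypoxia without HIF-1. The largest rises among named genes past the test were those of hsp-16.21 and of 2 inducible HSP70 genes. hsp-16.21 was 2.82 ± 0.65 higher in H (SD, n = 3, adjusted p = 0.00915). The adjacent and nearly identical inducible HSP70 genes F44E5.5 and F44E5.4 (chromosome II, 11757107 to 11761861 together) rose by 2.59 ± 1.47 (adjusted p = 0.0301) and 2.45 ± 1.59 (adjusted p = 0.0368; SD, n = 3 for both). F22B5.4 stood at 0.21 ± 0.48 (SD, n = 3; adjusted p = 0.793). C18E9.5 fell by 2.02 ± 0.73 (SD, n = 3; adjusted p = 0.00796), erp-44.3 by 2.07 ± 0.40 (SD, n = 2; adjusted p = 0.0137) and CYTB, the cytochrome b of the mitochondrial genome, by 1.86 ± 0.17 (SD, n = 3; adjusted p = 0.0148). Both HSP70 calls depended on single arrays: F44E5.5 and F44E5.4 were at 1.81 and 1.55 without hif-1 mutant array 3 (adjusted p = 0.112 and 0.125), and had adjusted p of 0.0983 and 0.0963 without array 2. The call of F44E5.5 was also lost with print layout centring (adjusted p = 0.07) and with named genes alone (0.0563).

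Further rises in the hif-1 mutant were those of pals-3 (2.39), dpsm-1 (1.79), C45G7.4 (1.74), F26G1.2 (1.67), srdh-1 (1.53), ZK84.1 (1.49) and C50B6.7 (1.42), with adjusted p from 0.0107 to 0.0462. Further falls were those of C44B7.5 (-3.07), T10B10.4 (-2.42), K05G3.2 (-2.12), Y106G6H.9 (-2.12), F07C4.6 (-1.76), C11H1.7 (-1.60) and B0416.3 (-1.56), with adjusted p from 0.0212 to 0.0430. In total 365 features passed, 99 higher and 266 lower (72.9% lower), and 4226 had an unadjusted p under 0.05. The 74 named genes among them, 36 higher and 38 lower, moved the same way on every array with a value, with the same limit. Of all features 37.0% did so. Of the 20 genes of largest change, 17 lost their call in at least 1 fit with an array left out, all but hsp-16.21 and, in the 7 and 5 fits that could test them, Y106G6H.9 and erp-44.3, and F26G1.2 was at 1.1 without array 3 (adjusted p = 0.157). The count was 58 without hif-1 mutant array 2, where the adjusted p of C18E9.5 was 0.0633 and that of CYTB 0.0695, and between 227 and 239 without hif-1 mutant array 1, wild type array 2 or vhl-1 mutant array 3. It was 102 (88.2% lower) with scaled arrays, where F44E5.5, F44E5.4, CYTB and erp-44.3 no longer passed (adjusted p 0.0841, 0.0957, 0.0720 and 0.0502), 97 after print layout centring, 122 without the places that hold no named spot, 18 with named genes alone and 138 with the hif-1 mutant arrays alone.

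In the vhl-1 mutant, where HIF-1 is not marked for degradation by this route, the comparison asks what hypoxia still changes. F44E5.5 and F44E5.4 showed the largest rises, 4.06 ± 1.09 and 4.03 ± 0.93 (SD, n = 3; adjusted p = 0.000788 for each), or 16.6-fold and 16.3-fold. F26A3.4 rose by 2.22 ± 0.89 (SD, n = 3; adjusted p = 0.0176), T01D3.3 by 1.88 ± 0.40 (adjusted p = 0.00253) and cest-12, of the carboxylesterase family, by 1.78 ± 0.98 (adjusted p = 0.0101). F22B5.4 was at 0.30 ± 0.38 (SD, n = 3; adjusted p = 0.623) and hsp-16.21 at 0.91 ± 0.68 (adjusted p = 0.194), neither past the test. Among the falls were those of Y106G6H.9, at -3.19 ± 0.82 (SD, n = 3; adjusted p = 0.000299), erp-44.3 at -2.76 ± 0.43 (adjusted p = 0.000254) and C18E9.5 at -2.61 ± 0.12 (adjusted p = 0.000365).

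Other large rises in the vhl-1 mutant were those of F40G12.4 (1.83), C07E3.3 (1.81), F58H1.7 (1.73), rcd-1 (1.61) and R06C1.6 (1.56), with adjusted p from 0.00266 to 0.0247. Other large falls were those of F49F1.7 (-3.02), lido-12 (-3.0), F09E10.5 (-2.98), M6.4 (-2.84), F37D6.7 (-2.78), K04H4.5 (-2.66) and Y40H7A.11 (-2.55), with adjusted p from 0.000600 to 0.0412. This genotype gave the most calls, 1915 features, 841 higher and 1074 lower, with 5638 at an unadjusted p under 0.05. All 442 named genes among them, 183 higher and 259 lower, moved the same way on every array with a value. The count was 1142, 413 and 547 without vhl-1 mutant array 1, 2 and 3, with 365 of the 413 and 477 of the 547 lower, and the adjusted p of F26A3.4 was 0.107 without array 2, 0.156 without array 3 and 0.0606 with scaled arrays. lido-12 was at -1.87 without array 3 (adjusted p = 0.314) and cest-12 had an adjusted p of 0.112 without array 2 and 0.103 without array 3. Of 21 named calls described here, nlp-55 of the gene lists included, 10 were lost in at least 1 such fit. It was 1189 without the places that hold no named spot, where higher features outnumbered lower ones (612 and 577), and 302 with named genes alone.

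**Figure D2:**
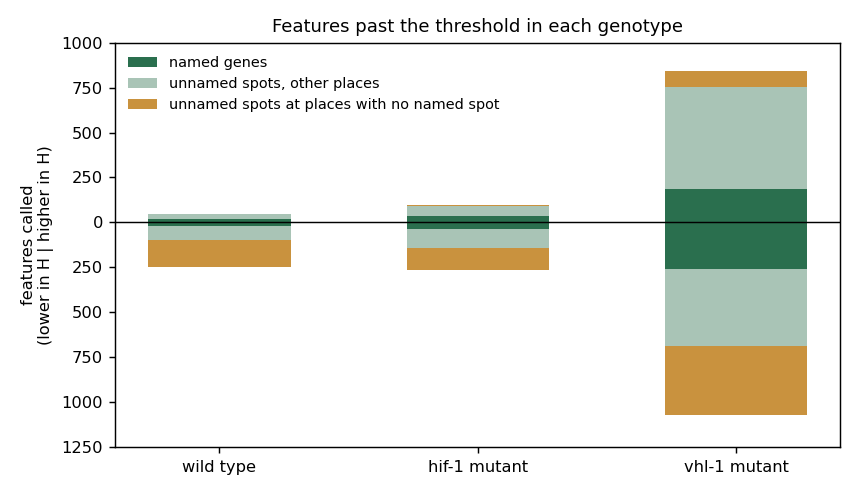
Number of features past the test in each genotype (vertical axis, higher in H above 0 and lower below), divided into named genes, unnamed spots and unnamed spots at print places without a named spot. Lower features number 249 of 296 in wild type, 266 of 365 in the hif-1 mutant and 1074 of 1915 in the vhl-1 mutant.

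C18E9.5, Y106G6H.9, erp-44.3 and C11H1.7 were among the 121 features that fell in all 3 genotypes, of which 6 were named, while 4 features rose in all 3. Of the 249 features lower in wild type, 124 were also lower in the hif-1 mutant and 231 in the vhl-1 mutant, where 3.18 and 12.8 would be shared if the calls were independent. Of the 47 higher in wild type, 5 and 17 were higher in the mutants (0.223 and 1.90 if independent), and no feature was called in opposite directions. The calls could not be independent in any case, because the genotypes share one residual spread per feature and one dye orientation. More sharing than these numbers is therefore no evidence of a shared response by itself. Much of this sharing lay at one kind of spot: spot numbers run through 32 print runs of 684 used places each, and at 87 of these places no run holds a named spot. The 2394 features at those places supplied 152 of the 296 wild type calls, 149 of them lower, and 82 of the 121 features lower in all 3 genotypes. In the hif-1 mutant they supplied 130 calls and in the vhl-1 mutant 471. At 6 of the 87 places, with 32 tested features each, the median change over the 3 genotypes lay between -2.11 and -1.92, and the 1 tested feature of another place was at -2.13. These 7 places, picked by their low medians and with 193 tested features, held 71 of the 82 features. The shared falls thus lay mostly at these 7 places and not at unnamed places in general.

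**Figure D3:**
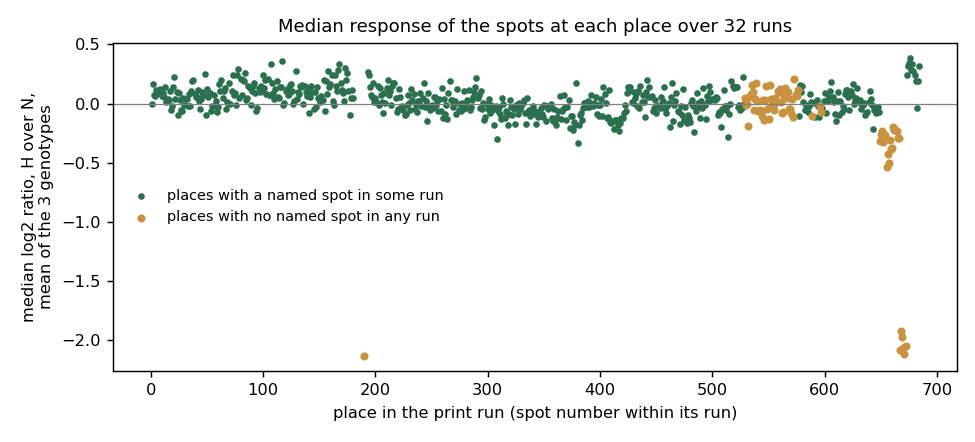
Median log2 ratio of H over N, averaged over the 3 genotypes (vertical axis), of the spots at each place of the print run (horizontal axis, spot number within its print run). The 7 places under -1, of which 6 have 32 tested features and 1 has a single one, all lack a named spot in every run.

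The difference between the hif-1 mutant and wild type asks which changes in hypoxia need HIF-1, and it is free of a dye effect that is alike on all arrays. F22B5.4 responded less in the hif-1 mutant (0.21) than in wild type (2.26), a difference of -2.05 (SE 0.516), and its arrays did not overlap, but the difference did not pass the test over all features (adjusted p = 0.603). It passed when adjusted over the list of HIF-1 targets alone, but as the single measured member its p is left unchanged by that adjustment. Passing there means only an unadjusted p under 0.05, as for 1239 features where chance gives 1043. That list was also drawn partly from this study, so the result is not independent evidence. The named genes with the lowest p, none past the test, were B0280.7 (0.49 in wild type, -1.44 in the hif-1 mutant; difference -1.92, SE 0.340, adjusted p = 0.446), slfl-3 (-1.54, adjusted p = 0.446), snrp-40.1 (-2.28), F41G3.10 (-1.77) and F01D5.5 (-1.68), the last 3 with an adjusted p of 0.473. The heat shock genes F44E5.5 and F44E5.4 differed by 0.55 and 0.49 (adjusted p = 0.974 for both).

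In this contrast limma called 0 features, with 1239 at an unadjusted p under 0.05 where chance gives 1043, and in 9.61% of features the arrays of the genotypes did not overlap where chance gives 10%. Among the 296 wild type responders alone, 2 differed in the hif-1 mutant, both nearer to 0 there: the unnamed spot probe_4338 (1.67 in wild type, -1.0 in the hif-1 mutant) and snrp-40.1 (1.47 and -0.82). These responders were chosen on the same wild type arrays, which favours a difference. Among the 1915 vhl-1 mutant responders 1 differed, and its difference had the same sign as its vhl-1 mutant response. It is therefore no case of such a response being weaker in the hif-1 mutant than in wild type. The count of 2 became 63 without wild type array 1, 15 without wild type array 2 and 0 without hif-1 mutant array 2. In simulated data with this spread and independent errors, 4% of differences of 1 log2 unit and 77.6% of those of 2 units were called. A difference of 1 unit was thus mostly not detectable with 3 arrays per genotype. Each simulation also held differences of up to 3 units, which ease the adjusted threshold. In the real contrast 0 features passed, so its threshold was stricter and fewer differences of 2 units may have been detectable.

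**Figure D4:**
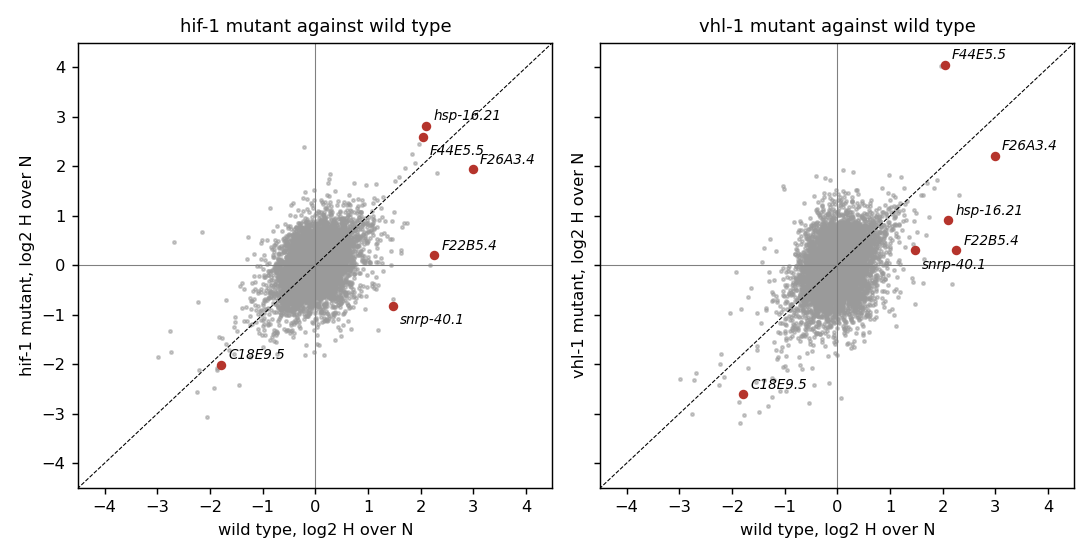
Mean log2 ratio of H over N of each named gene in wild type (horizontal axes) against the hif-1 mutant and the vhl-1 mutant (vertical axes), 3 arrays per genotype, with the dashed line for equal changes. F22B5.4 lies at 2.26 in wild type and at 0.21 and 0.30 in the mutants.

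Between the vhl-1 mutant and wild type, the question is how the response differs where HIF-1 is stabilised already. F22B5.4 differed by -1.96 (SE 0.516, adjusted p = 0.280). It too passed when adjusted over the list alone, with the same limits, since as its single measured member its p stays unadjusted. F44E5.4 and F44E5.5 were 2.07 and 2.02 higher in the vhl-1 mutant (adjusted p = 0.375 and 0.382). Both passed when adjusted over their list alone. These nearly identical genes are the 2 measured members of that list, so the adjustment covers only 2 tests. Small heat shock genes measured but not on that list went the other way without passing, with differences of -1.19 for hsp-16.21 (adjusted p = 0.536) and -1.52 for hsp-16.20 (adjusted p = 0.418). The named genes with the lowest p were R12E2.8 (-1.94, adjusted p = 0.193), B0280.7 (-1.90), nssp-76 (2.55), ZK470.6 (-1.72) and C05C9.1 (-1.86), the last 4 with an adjusted p of 0.250. In limma 1 feature passed over all features, the unnamed spot probe_21826. It was at 0.80 ± 0.34 in wild type and -2.07 ± 0.53 in the vhl-1 mutant (SD, n = 3; difference -2.87, adjusted p = 0.0284). The call was lost without any of 7 of the 9 arrays, each left out in turn, and with scaled arrays, replicate number as a block, print block centring or only the arrays of these genotypes. At an unadjusted p under 0.05 there were 2108 features, and 18.5% of features had arrays that did not overlap.

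The vhl-1 and hif-1 mutants differed most, by p, at F58G1.7 (1.54) and F58G1.8 (-2.04), both with an adjusted p of 0.714, then T04A6.2 (1.21), dlgr-1 (-1.81) and C14A4.12 (1.27), with adjusted p from 0.742 to 0.768. F22B5.4 differed by 0.09 (adjusted p = 0.985). limma called 0 features here, with 1336 at an unadjusted p under 0.05, and 0 in the F test of any difference among the 3 genotypes, with 1743 at an unadjusted p under 0.05; the lowest adjusted p of the F test was 0.0694, that of probe_21826. Leaving out hif-1 mutant array 3 gave 4 features in the first of these tests and 1 in the F test.

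The mean over all 9 arrays asks what moves in hypoxia whatever the genotype. Among the rises were those of the heat shock genes F44E5.5, by 2.89 (SE 0.303, adjusted p = 5.11e-05), F44E5.4, by 2.81 (adjusted p = 5.82e-05), and hsp-16.21, by 1.94 (SE 0.249, adjusted p = 0.000226). F26A3.4 rose by 2.38 and the carboxylesterase gene cest-24 by 1.89 (adjusted p = 0.000151 and 0.000906). F22B5.4 averaged 0.92 (adjusted p = 0.00929), with 2.26 in wild type and 0.21 and 0.30 in the mutants. C18E9.5 fell by 2.14 (SE 0.172, adjusted p = 7.85e-06), erp-44.3 by 2.23 (adjusted p = 2.18e-05), Y106G6H.9 by 2.39 (adjusted p = 2.3e-05) and CYTB by 1.80 (adjusted p = 9.15e-05). Further rises were those of T28C12.5 (1.89), T27F6.8 (1.87), F52E10.4 (1.78), dpsm-1 (1.60) and Y75B8A.6 (1.30), and further falls those of idpb-3 (-2.41), F41H10.4 (-2.39), C17C3.2 (-2.27), F49F1.7 (-2.09), K05G3.2 (-2.04), F09E10.5 (-1.93) and Y49F6C.6 (-1.90). In all 4493 features passed, 2304 higher and 2189 lower, with 7591 at an unadjusted p under 0.05; 480 of the 1222 named genes among them moved the same way on every array with a value. The count was 2660 without vhl-1 mutant array 2, 2699 without vhl-1 mutant array 3, 2751 without wild type array 2 and 1109 with named genes alone. A gene-specific dye effect would add to this mean on all arrays, since no array had the dyes exchanged.

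Across features, the mean response in wild type correlated with that in the hif-1 mutant at a Pearson r of 0.555 (Spearman 0.454) and with that in the vhl-1 mutant at 0.564 (0.419), and the mutants with each other at 0.669 (0.612). In named genes alone these were 0.430, 0.383 and 0.589. The 47 features higher in wild type had medians of 1.47 in wild type, 0.68 in the hif-1 mutant and 0.88 in the vhl-1 mutant, and the 249 lower ones of -1.92, -1.50 and -2.3. The features were chosen on the wild type values, so the medians of the mutants are the unselected ones.

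Gene lists fixed beforehand could be described only in part, because 21 of the 32 lists had no named member and 4 had the 3 members a list test needs. In the list of small heat shock proteins and inducible HSP70, both measured members, F44E5.4 and F44E5.5, rose in the hif-1 mutant, in the vhl-1 mutant and in the mean; in wild type they stood at 1.96 (adjusted p = 0.102) and 2.04 (adjusted p = 0.0887), past the test when adjusted over the list alone, and over all features when the wild type arrays were fitted alone (adjusted p = 0.034 and 0.0338). Of 18 neuropeptide-like genes, nlp-55 rose in the vhl-1 mutant (1.24, adjusted p = 0.0294), and nlp-49 (-0.63), nlp-51 (-0.54) and nlp-99 (-0.46) fell in the mean (adjusted p = 0.0353, 0.0446 and 0.0494); adjusted over the list alone, 3 members were higher and 2 lower in the vhl-1 mutant and 5 lower in the mean. Of 6 translation initiation factor genes, eif-2A (0.52) and eif-2Bepsilon (0.49) rose and eif-2D (-0.47) fell in the mean (adjusted p = 0.0452, 0.0283 and 0.0455); adjusted over the list alone, eif-2D was lower in wild type (-1.07, adjusted p = 0.0759 over all features) and 1 member was higher in the vhl-1 mutant. These calls depend on single arrays: of the 9 fits with an array left out, 3 ended that of nlp-55, 6 those of nlp-49, nlp-51 and eif-2Bepsilon, 7 that of eif-2A and 8 those of nlp-99 and eif-2D. The adjusted p in these fits reached 0.189 for nlp-55, 0.262, 0.120 and 0.154 for nlp-49, nlp-51 and nlp-99, and 0.127, 0.082 and 0.117 for eif-2A, eif-2Bepsilon and eif-2D. Replicate number as a block also ended the calls of nlp-99 and eif-2A in the mean. Of 5 cuticle collagen genes none passed over all features and 2 were higher in the hif-1 mutant when adjusted over the list alone (mean of the list 0.56). The respiratory chain genes cox-4, cox-6C, cox-7C and atp-1 averaged 0.07 in wild type, 0.18 in the hif-1 mutant and 0.23 in the vhl-1 mutant, and none passed.

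Apart from F22B5.4, described above, the measured members of the other lists did not pass over all features. rpn-13, a proteasome gene, was at 0.67 in the hif-1 mutant and 0.63 in the vhl-1 mutant (adjusted p = 0.218 and 0.180) and at 0.47 in the mean (adjusted p = 0.0582), and passed in all 3 when adjusted over the list alone. It is the single measured member of its list, so that adjustment leaves its p unchanged. In the mean it passed over all features with print block centring (adjusted p = 0.0267) and without hif-1 mutant array 1 (0.0467) or vhl-1 mutant array 1 (0.0197). The ribosomal gene rpl-37.1, the glucuronosyltransferase genes ugt-66 and ugt-67, the saposin-like gene spp-24 and the acyl-CoA synthetase genes acs-24 and acs-25 had mean changes of 0.08, -0.32, -0.18, 0.13, 0.09 and -0.15 over the genotypes. As a whole, 0 of the 28 tests of the 4 lists passed in limma with the preset correlation, with an estimated correlation or with fry, and 2 had an unadjusted p under 0.05 with the preset correlation. The lowest adjusted p with the preset correlation was 0.648, of the collagens in the hif-1 mutant (unadjusted p = 0.0419) and in its difference from wild type (0.0480), and with the estimated correlation every adjusted p was 0.942.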

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

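Chosen only after the results were seen were centring on the print layout, leaving out the places without a named spot, the size of the falls after centring and their share elsewhere, the comparison with the colour of the probes, the simulation of shared wild type arrays and the lists of gene families; the counts of other splits and the test of single wild type arrays were not.

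Differences between genotypes led to 6 results being listed here. probe_21826, an unnamed spot, differed by -2.87 between the vhl-1 mutant and wild type (adjusted p = 0.0284; no overlap between the 3 arrays of each). probe_4338, also unnamed, differed by -2.66 between the hif-1 mutant and wild type and passed among the 296 wild type responders but not over all features (adjusted p 0.446). snrp-40.1 differed by -2.28 in the same comparison and likewise passed in that set but not over all features (adjusted p 0.473). The 15 genes with names of the form idpp and a number averaged -0.49 in the hif-1 mutant minus wild type (adjusted p = 0.0112) and -0.71 in the vhl-1 mutant minus wild type (adjusted p = 0.000562). The 8 genes of the mitochondrial genome averaged -0.66 in the vhl-1 mutant minus the hif-1 mutant (adjusted p = 0.0299). With an estimated correlation these 3 family results all had an adjusted p = 0.991. Groups of 3 arrays were too small for a search for single outlying arrays.

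In wild type 249 of 296 calls were falls, 149 of them at places without a named spot and 100 elsewhere. At the former, print layout centring brought the median from -2.0 to -0.49 (24.6% of its size, with a median SE of 0.335 before and 0.308 after). These values thus go with the place, but the centring subtracts the low medians already seen at some of these places, so it is no separate test. The layout or whatever is printed there may account for the values. At the other places the median went from -1.83 to -1.79 (97.7%), which argues against a shift common to a run or place for those falls. A fault of single spots would stay after this centring, so it was not tested. The drop to 64 falls in all, 82.1% of the calls against 84.1% before, does not count for the layout there. The highest unadjusted p that passes also went from 0.000702 to 0.000185. Whether the unnamed places account for the predominance of falls stays open. Elsewhere 69.4% of the calls were falls (100 against 44 rises) and among named genes 18 of 34, while a new fit without those places gave 69 of 86 (80.2%). When the p-values of the main fit were adjusted anew without those places, the highest unadjusted p that passed was 0.000214. All 249 falls together had a median in the hif-1 mutant that was 78.4% of that in wild type, which a colour effect of the probes and a response shared by the genotypes would both give, and with no exchange of dyes these cannot be told apart.

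The differences of both mutants from wild type went together across features, as in B0280.7 (-1.92 in the hif-1 mutant and -1.90 in the vhl-1 mutant, neither past the test), with a covariance of 0.140 over 19473 features. Both differences use the same wild type arrays: in 1000 simulations with that sharing alone the covariance averaged 0.0842 and ran from -0.0365 to 0.223, so the shared arrays may account for it. Leaving out a wild type array gave 0.140 at the lowest, without array 3 (0.127 in simulation), and 0.244 without array 1, above the highest simulated value of 0.205. Whether 1 wild type array stands behind the pattern thus cannot be told apart from a departure common to both mutants, such as one from their strain background, because the answer differs with the array left out.

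The arrays were also divided in other ways, and for the responses each other division reversed the sign of some arrays. The real responses called 296, 365 and 1915 features in wild type, the hif-1 mutant and the vhl-1 mutant, and the highest of the other sign patterns called 0, 1 and 0; the real pattern was in each case the 1 of 4 with as many, too few patterns for a share under 0.05. For the mean response, 1 of 100 patterns drawn from 256, the real one, gave 4493 features and the highest other 719, which excludes random signs of the arrays at this level. A dye or print effect alike on all arrays would give the same outcome, so a response to hypoxia does not follow from it. The difference between the hif-1 mutant and wild type called 0 features, so all 10 of 10 splits gave as many, the highest other 29; that between the mutants also called 0, with 10 of 10 and a highest other of 0. The difference between the vhl-1 mutant and wild type, with 1 feature, was matched by only the real split, 1 of 10, the highest other giving 0. These 10 splits are too few for a share under 0.05. The F test called 0 features, a count that any division matches (100 of 100 drawn from 280, the highest other 10), so this says nothing about chance. Among the wild type responders, the real split gave 2 features that differed in the hif-1 mutant, 12 of 20 splits gave as many, and the highest gave 317. The 20 splits are too few for a share under 0.05, and the features compared change with the split; a split with many times the real count may point to a structure of the arrays other than genotype, which was not tested.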

How the results depend on the processing

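The tests with centring on print runs or on the print layout, with named genes alone and without the places that hold no named spot were chosen only after the results were seen. No result of a named gene or list that passed in the main or the alternative fit turned direction. Changes of sign in results that passed in neither were not counted. Values as deposited, all 9 values, no filter, each spot alone and robust eBayes kept the counts of the responses in wild type, the hif-1 mutant, the vhl-1 mutant and the mean within 1.5 times the reported one. Of 88 calls of named genes, scaling the arrays ended 23, print layout centring 25, leaving out unnamed places 16 and testing named genes alone 37, and leaving out 1 array ended 13 to 26 of those that could be tested. Signal over background is unknown here, so what it limits could not be assessed.

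The wild type count of 296 became 540 with scaled arrays, 482 at a threshold of 0.10, 78 with print layout centring, 86 without unnamed places and 0 in limma with named genes alone (769 at an unadjusted p under 0.05). The hif-1 mutant count of 365 became 102 with scaled arrays, 1224 at 0.10, 97 with print layout centring, 122 without unnamed places, 18 with named genes alone and 138 with its own arrays. The vhl-1 mutant count of 1915 became 3460 at 0.10, 1189 without unnamed places and 302 with named genes alone, and the mean count of 4493 became 1109 with named genes alone. All 86, 122 and 1189 features called without unnamed places were among those reported. The 1 feature of the vhl-1 mutant minus wild type was lost (0) with scaled arrays, replicate number as a block, print block centring and the arrays of these genotypes alone, with 2158, 2108, 1969 and 2725 features at an unadjusted p under 0.05. It is an unnamed spot and so was not in the test of named genes alone, which called 0 (762 at an unadjusted p under 0.05). The F test gave 1 at 0.10.

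The 2 wild type responders that differ in the hif-1 mutant became 9 with values as deposited, 17 with scaled arrays, 10 with all 9 values, 10 with robust eBayes, 24 at 0.10, 9 with the replicate block, 5 with print block centring, 13 with print layout centring, 18 without unnamed places, 0 with named genes alone, where no wild type gene passes, and 1 with the arrays of these genotypes alone. The correlation of wild type and hif-1 mutant responses was 0.477 with print layout centring, 0.489 without unnamed places and 0.430 in named genes; that of wild type and vhl-1 mutant 0.615 with print block centring, 0.473 without unnamed places and 0.383 in named genes; that of the mutants 0.722, 0.632 and 0.589. Fewer features tested, and fewer that change alike, come with leaving out unnamed places or spots; for the other changes the cause was not tested.

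With 1 array left out the counts ran from 82 (without wild type 3) to 377 (without hif-1 mutant 2) in wild type, with 107 without wild type 2, from 58 (without hif-1 mutant 2) to 349 in the hif-1 mutant, and from 413 (without vhl-1 mutant 2) to 2608 in the vhl-1 mutant. They ran from 2660 (without vhl-1 mutant 2) to 4191 in the mean. The differences gave 0 to 1 for the hif-1 mutant minus wild type (1 without wild type 1), 0 to 1 for the vhl-1 mutant minus wild type, 0 to 4 for the mutants (4 without hif-1 mutant 3) and 0 to 1 for the F test. Wild type responders that differ in the hif-1 mutant ran from 0 (without hif-1 mutant 2) to 63 (without wild type 1). The correlations ran from 0.421 to 0.577, from 0.416 to 0.577 and from 0.570 to 0.667. Gene lists stayed at 0 throughout.

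The replicate numbers did not pair the arrays: after removing genotype means, arrays of the same number correlated between -0.199 and 0.269, and 3 of 9 arrays were closest to an array of their own number. With replicate number as a block the counts were 318, 426 and 1826 in the 3 genotypes, 0, 0 and 0 for the differences, 4099 for the mean and 0 for the F test. Of the named genes it ended 5 calls, W04E12.4, F02D10.2 and T08G3.6 in wild type (adjusted p = 0.0606, 0.0582 and 0.0562) and nlp-99 and eif-2A in the mean (0.0613 and 0.057), and added 4, F44E5.5 and F44E5.4 in wild type (adjusted p = 0.00286 and 0.00853), nlp-51 in the vhl-1 mutant (0.0428) and rpn-13 in the mean (0.0324).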

Other observations

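The tests of neighbouring genes and of gene families were chosen only after the results were seen.

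Of the 32 measured carboxylesterase genes named cest, 5 rose in the mean over the genotypes, cest-24 by 1.89, cest-12 by 1.30, cest-27 by 0.96 (adjusted p = 0.000485), cest-35.2 by 0.62 and cest-31 by 0.42, and 0 fell; of all 7179 named genes 593 rose and 629 fell (1222 in all). As a list they did not pass (mean 0.21, adjusted p = 0.337). Of the 8 measured genes of the mitochondrial genome, CYTB was the 1 that passed, with -1.86 in the hif-1 mutant, -2.28 in the vhl-1 mutant and -1.80 in the mean. Of 13 nuclear genes of respiratory complex I, 1 rose and 1 fell in the mean. hsp-16.20, of the small heat shock family, was at 1.65 in wild type (adjusted p = 0.0959) and rose by 0.85 in the mean (adjusted p = 0.0391).

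Among the 15 idpp genes, idpp-9 and idpp-13 fell in the vhl-1 mutant, and the family averaged -0.54 there (adjusted p = 0.0347, and 0.991 with an estimated correlation). Of the 168 tests of the 24 lists made from the measured names, 4 passed with the preset correlation and 0 with an estimated one.

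Genes next to each other on a chromosome responded alike to a small degree. Over 2878 pairs of neighbouring genes the mean response correlated at an r of 0.162 (permutation p = 1e-05, the smallest that 100000 permutations can give; adjusted p = 1e-05). If the order of printing caused this, pairs printed in different runs and more than 30 places apart should not correlate, but 1975 such pairs kept an r of 0.105 (permutation p = 1e-05, adjusted 1e-05), so printing may account for part of the first value only. A colour effect alike on all arrays would cancel in the difference between the hif-1 mutant and wild type, where these pairs had an r of 0.0693 (permutation p = 0.001, adjusted 0.001). Pairs without a shared name stem, 1953 of them, had an r of 0.108 (permutation p = 1e-05). Genes known only by a sequence name have no such stem and were kept, so this value cannot decide about related sequences. Probes for related sequences remain possible because sequences were not compared here, and a common control of neighbouring genes is a hypothesis that was not tested further.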
